A study of Homo sapiens with 6 samples.

How the data were processed

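RNA of the Hodgkin lymphoma cell line L1236 was measured on 6 gene expression arrays, 1 array for each of 3 agents at each of 2 times. Per the labels' protocols, cells were pelleted and suspended in serum-free medium with leukotriene D4 (LTD4) at 100 nM or with 0.1% methanol, the vehicle, and total RNA was extracted with TRIzol. The labels do not say how the cells called untreated were handled, in particular whether their medium held serum.

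The deposited table holds gene-level intensities on a linear scale, 1 column per array, for 33297 probesets. Per the submitters' processing notes, RMA and the Affymetrix Expression Console software were used, with no version given. The name of the deposited table carries the word PLIER, the name of another summary method, and its linear values with exact zeros differ from the log scale that RMA gives. Which of the 2 methods made the deposited intensities, and how they were normalized between arrays, is not given in the sources used here. A second deposited table with the value of each probeset on each array was identical to the first in all 199782 values. The deposited fold columns, per the file headers made by the authors for pairs of arrays, equalled the signed ratio of the 2 intensities in each of 33237 to 33242 probesets that had a fold, within an absolute tolerance of 1e-06, so they held no further information. The genome build and annotation release of the coordinates are not given in the sources used here.

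A probeset was used when the deposited annotation named exactly 1 gene symbol for it. This held for 19479 probesets, while 1032 named several symbols and 12786 named none. Symbols were updated through the Entrez identifier to those of GRCh38.p14 for 19079 of them, and the file's symbol was kept otherwise. Where several probesets carried a symbol, the probeset with the highest mean was taken, which left 18604 genes. Probesets with blank annotation were left out.

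Values were analysed as log2(intensity + 16), which understates the change of dim genes, and every difference below is on that scale. A gene was tested when its highest value on the 6 arrays reached the 95th percentile of the antigenomic control probesets, which match no human sequence. The percentile was taken over 45 such probesets and all arrays and came to 10.32, an intensity of 1263, and 3584 genes passed. The limit is strict, because the median antigenomic probeset lay between 40.7 and 59.8 on each array. It left out dim members of several gene lists, and because it looks at the highest array, a gene could pass through a single array. No scaling beyond the deposited one was applied in the main analysis.

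Each group was a single array, so differences between 2 arrays had no test and no replicate error. A gene counted as changed by LTD4 at a time when the LTD4 array lay at least 1 log2 unit (2-fold) above, or below, both the methanol and the untreated array of that time. For 26 gene lists fixed before the data were examined, the median difference of the measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. That percentile describes these arrays and is no p-value. It was computed for lists with at least 3 measured members.

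Tests came from an additive linear model of agent and time over the 6 arrays, fitted with limma (lmFit and eBayes) with 2 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. In this fit limma estimated infinite prior degrees of freedom, so all genes had the same standard error: 0.18 for 8 h against 1 h and 0.22 for comparisons between agents. Array-wide shifts shared by many genes made up much of the residual, and after each array was centred on its median the prior degrees of freedom were 9.32. Nothing in the labels says that cultures were repeated, so p-values measure only the spread between these arrays, which may be technical, and they treat the 3 agents as repeats for the time effect and the 2 times as repeats for the agent effects. Gene lists were tested in the time fit with camera, with a preset correlation between genes of 0.01 and with an estimated one.

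Before the data were examined, the rule for named genes was set. It took up to 15 genes higher and 10 lower by the LTD4 rule at each time, the 5 highest and 5 lowest for methanol against untreated at each time, and up to 15 higher and 15 lower genes among those past the threshold in the fits that moved the same way on every pair of arrays. It also took up to 4 measured members of each list with the greatest difference, and CYSLTR1, CYSLTR2 and EGR1 in every case.

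Alternatives set before the data were examined were the second deposited table, offsets of 1 and 64, no filter, a filter on the mean at the median of all probesets, quantile normalization and centring each array on its median. A change of 1.5-fold in place of 2-fold, methanol alone, untreated alone or their mean as reference, eBayes with a trend or robust, a fit without the block, and fits without each array or each agent in turn were also set then. The remaining ones were chosen after seeing the data and are named as such.

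The fits and the LTD4 rule were tested on simulated data made from the 3584 tested genes with 200 changed genes. Changes of 2 log2 units were recovered in 100% of genes for 8 h against 1 h, in 100% for LTD4 against methanol over both times, in 99.5% for methanol against untreated over both times and in 100% by the LTD4 rule at 1 h. Changes of 1 log2 unit were recovered in 91.5%, 81.5%, 82.5% and 31%, in the same order. Changes of 0.5 were recovered in 48.5% for 8 h against 1 h, in 0% in both fits between agents and in 1.5% by the LTD4 rule. Genes not changed in the simulation were called as well: 4 to 10 for 8 h against 1 h, 0 to 6 and 0 to 7 in the fits between agents and 3 or 4 by the LTD4 rule. The simulated spread came from the residuals of a fit to arrays centred on their medians, which also hold real effects present at 1 time only. It was drawn separately for each gene, so the simulated arrays held no array-wide shifts. Such shifts made up much of the residual in the main fits, so recovery and calls there can differ from these values. The precision of every value is limited by the number of arrays. Computations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.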

Results

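Gene expression was measured in L1236, a cell line derived from the malignant B-lineage cells of Hodgkin lymphoma, after 1 h and 8 h with leukotriene D4, with its methanol vehicle, or without treatment. LTD4 is a cysteinyl leukotriene, a lipid mediator made from arachidonic acid that acts on G protein-coupled receptors. Each of the 6 combinations of agent and time was measured on 1 array, so no group had replicates and no difference between 2 single arrays could be tested. The median intensity of all probesets was 188 on the untreated, 228 on the methanol and 217 on the LTD4 array at 1 h. At 8 h it was 154, 223 and 210, in the same order. Over all 33297 probesets, Spearman correlations between arrays ranged from 0.957 for methanol at 1 h with untreated at 8 h to 0.991 for methanol with LTD4 at 8 h. Probesets are not independent replicates, and these correlations only describe the arrays. The median of the 3584 tested genes also shifted between arrays. It shifted by 0.11 for LTD4 minus methanol at 1 h and by -0.10 at 8 h. For methanol minus untreated it shifted by -0.21 at 1 h and by 0.27 at 8 h. Over all 18604 genes these medians were 0.01, -0.08, 0.08 and 0.36, so the sign for methanol at 1 h turned. At 1 h the first quartile of all probesets was 66.5 on the untreated and 89.1 on the methanol array. The third quartile was 667 and 650. This difference varied with intensity, which centring by 1 value per array does not remove. All values are on the log2 scale of the deposited intensities with an offset of 16, and for the main comparisons, RNA classes and lists with calls, counts after centring each array on its median are also given.

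The first comparison asked which genes LTD4 changed within 1 h. EGR1, a zinc finger transcription factor and immediate early gene, had an intensity of 9692 with LTD4, against 2882 with methanol and 2112 in untreated cells, differences of 1.74 and 2.19. KLF10, a Krüppel-like transcription factor induced by TGF-beta, was higher by 1.52 and 1.18, and BTG2, an antiproliferative early gene, by 1.08 and 1.04. These 3 genes were the ones at least 2-fold above both references, and 0 genes were at least 2-fold below both. EGR1 lies on chromosome 5 at 137829080-137832903, KLF10 on chromosome 8 at 103730188-103737128 and BTG2 on chromosome 1 at 201541242-201545353, in coordinates of a build not given in the sources used here. KLF10 and BTG2 passed the background limit on the LTD4 array at 1 h alone, where their intensities were 1332 and 1921.

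**Figure D1:**
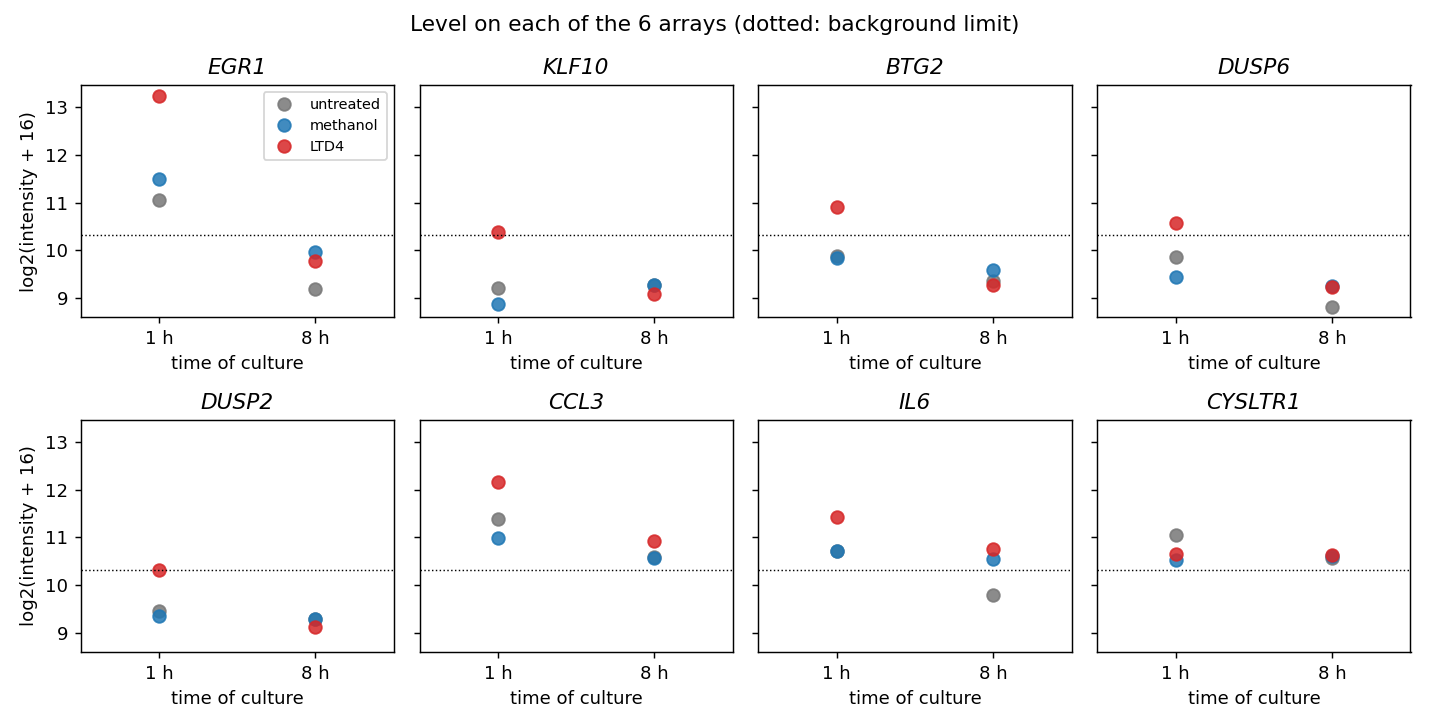
Log2(intensity + 16) of 8 genes on each of the 6 arrays, by time on the x axis and by agent in colour, with 1 point per array. The dotted line is the background limit of 10.32. EGR1, KLF10 and BTG2 lay above both other arrays of 1 h by at least 1.04 with LTD4, while CYSLTR1 at 1 h was highest on the untreated array.

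At a 1.5-fold limit 15 genes were above both references and 0 below, and after centring 10 and 0. Centring ended the call of 6, BHLHE40, GADD45B, GAS5, SNORD14C, SNORD54 and SNORD68, and added CD274. The 15 genes included DUSP2 (0.97 against methanol and 0.87 against untreated) and DUSP6 (1.12 and 0.71), phosphatases that switch off MAP kinases, and GADD45B (0.70 and 0.63), a stress and NF-kB inducible gene. The inflammatory cytokine IL6 was higher by 0.72 and 0.72 and the chemokine CCL3 by 1.17 and 0.77. The row of CCL3L3, a nearly identical copy of CCL3 that can share its signal, was higher by 0.97 and 0.88. BHLHE40, a transcriptional repressor, was higher by 0.68 and 0.60. The remaining 5 were GAS5 and the small nucleolar RNAs SNORD13P3, SNORD14C, SNORD54 and SNORD68. The GAS5 row spans only 172101114-172101188 on chromosome 1, between the rows of SNORD47 at 172100130 and SNORD44 at 172101729, so it does not stand for the whole host transcript. Below the background limit, NR4A3 (1.51 and 1.60), an orphan nuclear receptor, FOSB (1.42 and 1.53), an AP-1 subunit, NAB2 (1.44 and 1.80), a repressor of EGR1, and TRIB1 (1.76 and 1.41), a pseudokinase, were also at least 2-fold above both references. Genes below the limit, those at 1.5-fold, and JUNB, MCL1 and JUN in what follows were chosen after their values were seen, unless they led a fixed list.

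All 19 measured members of the list of immediate early transcription factors and regulators were higher with LTD4 than with methanol at 1 h, with a median of 0.45. That median lay at percentile 100 of random lists of the same size, whose own median was 0.12. Against the untreated array 15 of 19 were higher, with a median of 0.25 at percentile 99.99. IER2 (0.96 against methanol, 0.43 against untreated) and JUNB (0.91 and 0.39) were among the higher members. MCL1 (0.58 and 0.17) was also above both arrays. JUN differed by 0.24 from methanol and by -0.28 from untreated. IER5 lay at -1.24 against the untreated array and 0.14 against methanol. Of the ERK feedback list DUSP2 and DUSP6 passed the background limit, both on the LTD4 array at 1 h alone. Without the filter its 20 members had medians of 0.30 against methanol and 0.38 against untreated, both at percentile 100.

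The list of NF-kB feedback genes and targets had a median of 0.25 against methanol, at percentile 99.96, with 11 of 11 members higher. Against untreated its median was 0.03 at percentile 93.76. Without the filter its 20 members had medians of 0.22 at percentile 99.97 against methanol and 0.14 at percentile 99.65 against untreated. TNFAIP3, the A20 inhibitor of NF-kB signalling, differed by 0.55 and 0.59, and REL by 0.38 and 0.29. The cytokine and chemokine list had a median of 0.22 against methanol, at percentile 99.41, and of 0.02 against untreated, at percentile 90.67. Without the filter its 35 members had medians of -0.02 against methanol, at percentile 24.07, and 0.15 against untreated, at percentile 94.6. Within it TNF differed by 0.39 and 0.42 and CCL2 by 0.35 and -0.06. Calcium, NFAT and CREB targets had a median of 0.28 at percentile 99.03 against methanol and of 0.03 at percentile 89.22 against untreated, with RGS2 at 0.31 and 0.41. Without the filter 15 members had 0.15 at percentile 98.94 and 0.22 at percentile 98.4. Of 14 measured Hodgkin cell markers, CD274, which encodes PD-L1, stood highest at 0.74 and 0.57. The list as a whole had a median of 0.12, at percentile 60.88.

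**Figure D2:**
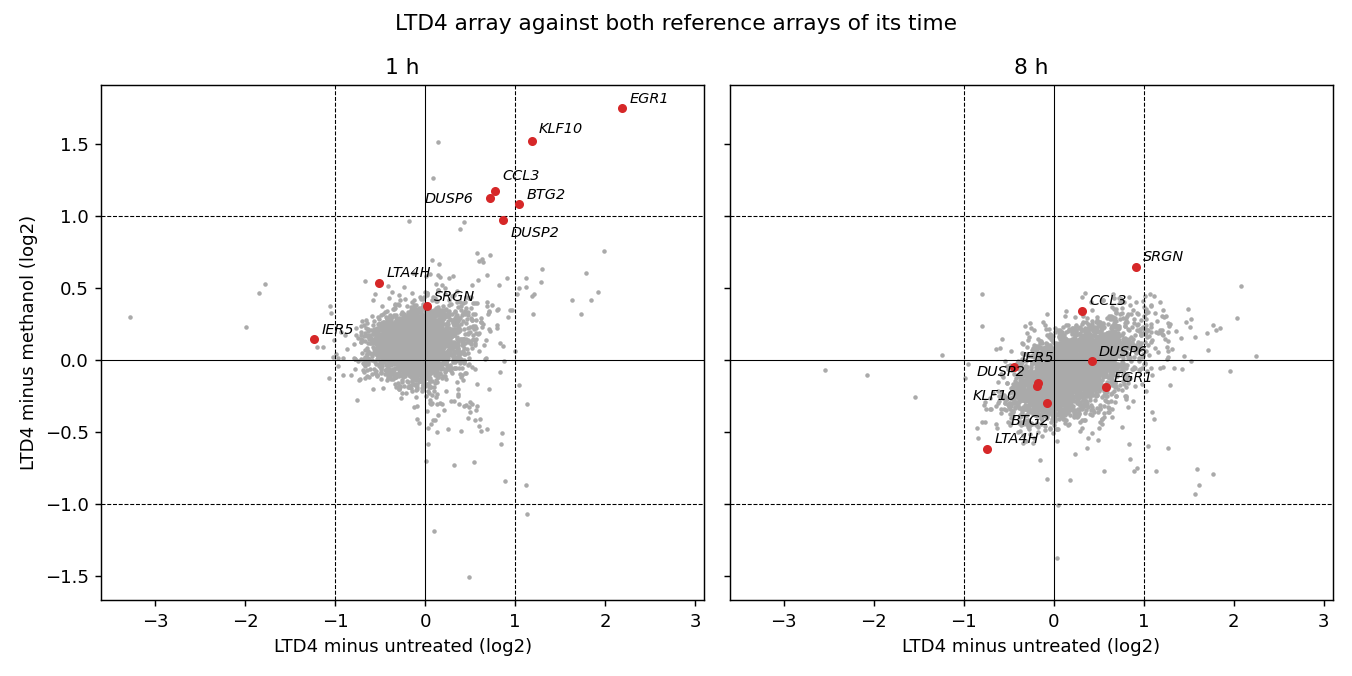
Difference of the LTD4 array from the methanol array (y axis, log2) against its difference from the untreated array (x axis, log2) at 1 h and 8 h. Each of the 3584 genes above the background limit is 1 point, dashed lines mark 1 log2 unit, and red points are named genes. EGR1 at 1.74 and 2.19 stands farthest to the upper right at 1 h, and at 8 h 0 genes lie beyond both lines in the same direction.

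The count of 3 rested on the background limit and on the array taken as the odd one. Without the filter 10 genes were higher and 3 lower, after centring 2 were higher because BTG2 then differed from methanol by 0.97, and by the same rule the methanol array at 1 h stood apart in 5 genes and the untreated array in 21. In simulated arrays without array-wide shifts the rule called 3 or 4 unchanged genes, as many as the 3 found, so the count alone does not set EGR1, KLF10 and BTG2 apart from spread between arrays.

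At 8 h the same comparison gave 0 genes higher and 0 lower by 2-fold, also after centring. At 1.5-fold SRGN, the proteoglycan serglycin of secretory granules, was higher by 0.65 against methanol and 0.91 against untreated. LTA4H, which makes leukotriene B4, was lower by the same rule, at -0.62 and -0.74. After centring 2 genes, SRGN and CES1, were higher by that rule and 0 lower, so the LTA4H call was lost. EGR1 had an intensity of 865 with LTD4, 990.1 with methanol and 573 without treatment, all below the background limit of 1263. The immediate early list had a median of -0.13 against methanol, at percentile 40.28, with 4 of 19 members positive, and BTG2 at -0.30 and MCL1 at -0.25 were its members farthest from 0. NF-kB genes had a median of -0.16, at percentile 11.12, with 0 of 11 positive. The inflammatory chemokine CXCL10 differed by 0.44 from methanol and 0.83 from untreated. Without the filter 2 genes were higher and 1 lower, each of low intensity.

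CYSLTR1, the high-affinity receptor of LTD4, had intensities of 2116 in untreated, 1457 in methanol and 1605 in LTD4 cells at 1 h. At 8 h they were 1499, 1551 and 1567. CYSLTR2, the second cysteinyl leukotriene receptor, had intensities of 4411, 3482 and 4223 at 1 h and of 3799, 4364 and 3657 at 8 h. ALOX15, a lipoxygenase of arachidonic acid, was among the brighter genes of the list with 9721, 6405 and 7206 at 1 h. The 6 measured members of the leukotriene and eicosanoid list had a median of 0.22 against methanol at 1 h, at percentile 97.71, but of -0.32 against untreated, at percentile 1.81. In the measured members LTA4H stood at 0.54 and -0.51. Without the filter 21 members had medians of -0.06 and 0.03. At 8 h the median against methanol was -0.17, at percentile 6.82.

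The LTD4 effect at 8 h minus that at 1 h, both against methanol, was at least 1 log2 unit in 31 genes, 4 positive and 27 negative. The negative ones included EGR1 at -1.94, KLF10 at -1.70, BTG2 at -1.38, DUSP6 at -1.13, DUSP2 at -1.13 and JUNB at -1.10. Many others were small nucleolar RNAs, such as SNORA31 at -2.06 and SNORD15B at -1.92. The positive ones were CES1 at 2.02, CTAG2 at 1.36, NEUROD2 at 1.05 and a predicted gene. The median of the 3584 tested genes was -0.21, and after centring 9 were positive and 14 negative. Without the filter 135 were positive and 77 negative. The design has no replicate for this difference, so it was not tested.

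In the fit over both times, LTD4 against methanol gave 0 genes higher and 0 lower by limma. An unadjusted p below 0.05 was found in 13 genes, a smaller share than the 0.05 due without any effect. The shared standard error of 0.22 holds array-wide shifts, so the 0 does not show that LTD4 had no effect. EGR1 differed by 0.78 with a standard error of 0.22 (adjusted p = 0.9999), positive at 1 of 2 times, and CYSLTR1 by 0.08 (adjusted p = 0.9999). Without the LTD4 array of 8 h the EGR1 difference was 1.66 (adjusted p = 0.0162, the lowest over its alternatives, whose highest was 1), and without the LTD4 array of 1 h it was -0.11. Centring gave 0 genes, and no filter gave 1 higher and 2 lower. The fit averages the 2 times, so a change at 1 h alone adds to its residual.

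The vehicle comparison showed how far 2 arrays without LTD4 lay apart. RPPH1, the RNA of RNase P, was lower with methanol than in untreated cells, at -3.58 at 1 h and -2.47 at 8 h. RMRP, the RNA of RNase MRP, stood at -2.31 and -1.97, and the spliceosomal RNAs RNU5E-1 at -2.31 and -1.27 and RNU4B1 at -2.22 and -1.29. C/D box small nucleolar RNAs, many of which guide ribosomal RNA methylation, were higher: SNORD41 by 1.42 and 2.57, SNORD54 by 1.18 and 2.51, SNORD13 by 1.41 and 2.35 and SNORD50A by 1.45 and 1.91. Among protein-coding genes CTAG2, a cancer-testis antigen, was higher by 2.20 and 1.74, CES1, a carboxylesterase, by 1.99 and 1.56, FAM110C by 1.98 and 1.11 and NEUROD2, a neuronal transcription factor, by 1.73 and 1.60. H3C7, a replication-dependent histone gene, stood at -1.43 and -0.93. In all, 21 genes were higher and 20 lower by 2-fold at 1 h, or 34 and 11 after centring and 338 and 38 without the filter, and 77 higher and 6 lower at 8 h, or 31 and 8 after centring and 700 and 8 without the filter.

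Over both times limma found 68 genes higher and 13 lower with methanol, each on the same side at both times. Centring each array moved the split to 203 higher and 195 lower, with 79 genes called in both. RPPH1 fell by 3.03 (adjusted p = 4.55e-38) and RMRP by 2.14 (adjusted p = 1.82e-18), while SNORD41 rose by 2.00 (adjusted p = 4.52e-16) and CTAG2 by 1.97 (adjusted p = 8.36e-16), all with a standard error of 0.22. After centring their adjusted p were 7.89e-07, 7.04e-06, 1.93e-04 and 0.00174, and the highest over their alternatives were 1.00e-05, 2.38e-05, 0.00257 and 0.0113. Of 26 measured C/D box small nucleolar RNAs 15 rose and 0 fell, or 19 and 0 after centring. Of 7 RNase P, RNase MRP, 7SK and spliceosomal RNAs 0 rose and 4 fell, RPPH1, RMRP, RNU5E-1 and RNU4B1, or 5 after centring. RN7SK stood at -0.50 without a call (adjusted p = 0.347) and was the one added by centring, and RNU2-1 and RNU2-2, which hold the same values, stood at 0.28 at 1 h and 0.31 at 8 h. Of 12 H/ACA box RNAs 2 rose and 1 fell, or 3 and 1 after centring. SNORA31, which fell, lost the call after centring at -0.87 and stood at -0.05 without the methanol array of 1 h. Of 35 histone genes 1 rose and 4 fell, H3C7 by 1.18, H3C12 by 1.08, H4C6 by 1.04 and H2AC8 by 0.97, and after centring 2 rose and 16 fell. These 4 lost the call without the methanol array of 1 h, where they stood at -0.81 to -0.95. Of 68 cytoplasmic ribosomal protein genes 0 rose and 1, RPS29, fell by 0.96, or 1 and 3 after centring. RPS29 lost the call without either methanol array, at -0.98 and -0.95. Of 28 mitochondrial ribosomal protein genes 1 rose and 0 fell, also after centring. These RNA classes were formed after the data were seen. The LTD4 arrays also lay on the same sides of the untreated ones, with medians of 0.92 at 1 h and 0.84 at 8 h for the C/D box class and -1.79 and -1.24 for the class of RPPH1 and RMRP. Both comparisons share the single untreated array of each time, so an untreated array that stands apart would give this likeness alone.

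**Figure D3:**
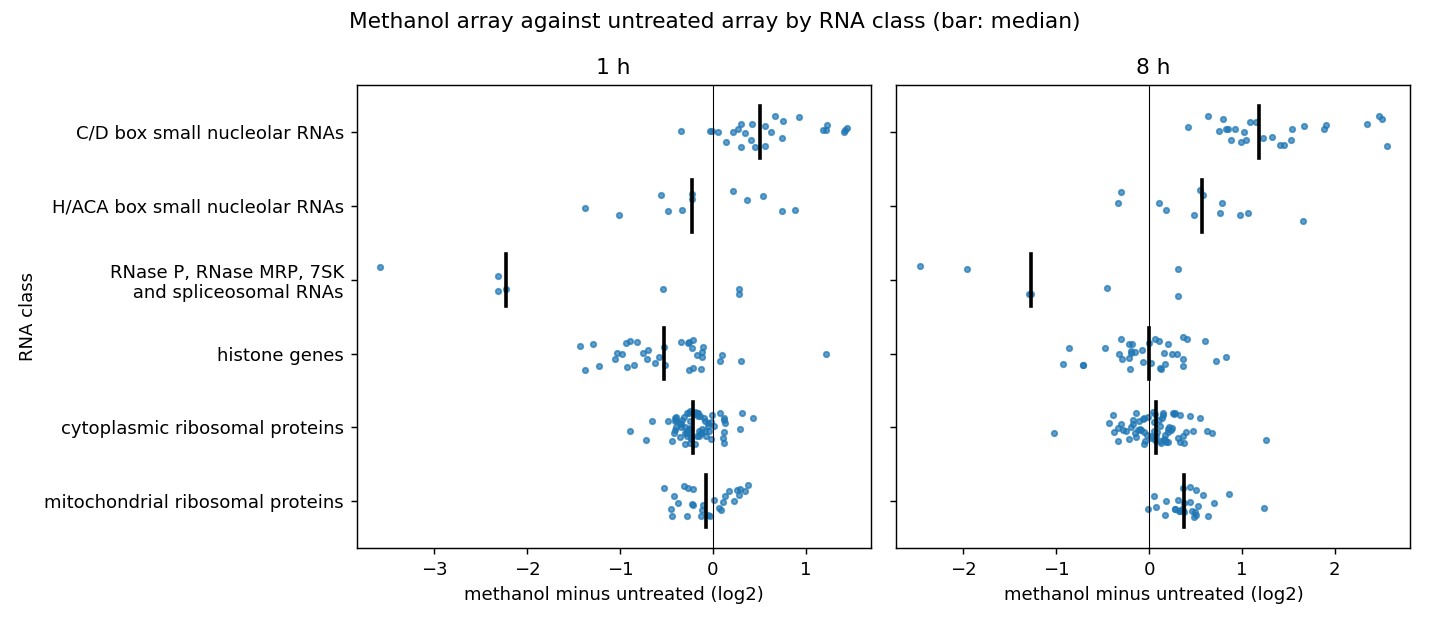
Difference between the methanol and the untreated array (x axis, log2) at 1 h and 8 h for the measured members of 6 RNA classes, 1 point per gene, with a black bar at the median. C/D box small nucleolar RNAs have medians of 0.51 and 1.19, and RNase P, RNase MRP, 7SK and spliceosomal RNAs of -2.22 and -1.27. Points are spread vertically at random.

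DDIT3, the stress transcription factor CHOP, rose by 1.08 with methanol (adjusted p = 1.23e-04), higher at both times, and was 1 of the 8 measured members of the stress response list to pass, also after centring, with 0 lower. IER5, an immediate early gene, fell by 0.89 (adjusted p = 0.00493), mainly at 1 h, where it stood at -1.38 against -0.39 at 8 h. IER5 lost the call without the methanol array of 1 h, at -0.59, without the untreated array of 1 h, at -0.44, and without either LTD4 array, at -0.89. It was the 1 of 19 immediate early genes called, and after centring 1 was higher, SRF, and 1 lower. DDIT3 lost it without the methanol array of 8 h, at 0.89. The 4 measured genes of formaldehyde and alcohol metabolism had 0 calls, and CAT, MTHFD1, ADH5 and ESD had a median of -0.03. Adjusted over the list alone, the leukotriene list gave 1 lower gene, and after centring LTA4H and ALOX15 were called lower. Without the untreated array of 1 h the fit called 343 genes, and without the methanol array of 8 h it called 38.

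The last comparison set 8 h against 1 h over the 3 agents and asked what changed with time in culture. EGR1 fell by 2.28 (SE 0.18, adjusted p = 3.27e-32), lower in 3 of 3 agents, and JUN fell by 1.24 (adjusted p = 7.15e-09), also in 3 of 3. On each array of 8 h EGR1 lay below the background limit. The chemokine CXCL10 rose by 1.65 (adjusted p = 2.37e-16) and GPR15, a chemoattractant receptor, by 1.34 (adjusted p = 1.90e-10), each in 3 of 3. After centring the adjusted p of EGR1, JUN, CXCL10 and GPR15 were 0.00144, 6.65e-05, 4.82e-04 and 8.97e-05, and the highest over their alternatives were 0.00251, 0.00486, 9.71e-04 and 0.00148. In the fit without centring all genes share 1 standard error. ARHGEF3 rose by 0.93 (adjusted p = 1.61e-04) and CPOX, an enzyme of heme synthesis, by 0.81 (adjusted p = 0.0023). Limma called 34 genes higher and 29 lower, of which 31 and 28 moved the same way in all 3 agents. After centring there were 61 higher and 96 lower, and 55 genes were called in both. The balance of directions turned with other settings: 62 higher and 258 lower without the filter, 42 and 91 with a filter on the mean, and 167 and 20 without both untreated arrays.

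Of 19 immediate early genes 5 fell, EGR1, JUN, BTG2, IER5 and GADD45B, and 0 rose. Adjusted over the list alone, 8 fell, and after centring 8 fell over all genes. BTG2 fell by 0.80 (adjusted p = 0.0023), with -1.64 between the LTD4 arrays against -0.52 between the untreated and -0.25 between the methanol arrays. Without the LTD4 arrays BTG2 stood at -0.39 and lost the call. EGR1 stood at -3.46, -1.85 and -1.53. IER5 lost the call without any 1 of the 6 arrays, at -0.35 without an untreated, -0.75 without an LTD4 and -0.84 without a methanol array. GADD45B lost it without the LTD4 arrays, at -0.49, and without the methanol arrays, at -0.83. Camera gave the list an adjusted p of 3.00e-25 with the preset correlation, and an adjusted p = 0.905 with an estimated correlation. Of 11 cytokines and chemokines CXCL10 rose, and CCL3 fell by 0.81 (adjusted p = 0.0023) and TNF by 0.61 (adjusted p = 0.0470). CCL3 lost the call without the LTD4 arrays, at -0.59, and without the block, and TNF lost it without any 1 of the 6 arrays, at -0.50 to -0.79. After centring 1 rose and 3 fell in this list. DUSP6 fell by 0.85 (adjusted p = 8.98e-04), with -1.33, -1.04 and -0.19 between the LTD4, untreated and methanol arrays, and without the LTD4 arrays it stood at -0.62 and lost the call.

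**Figure D4:**
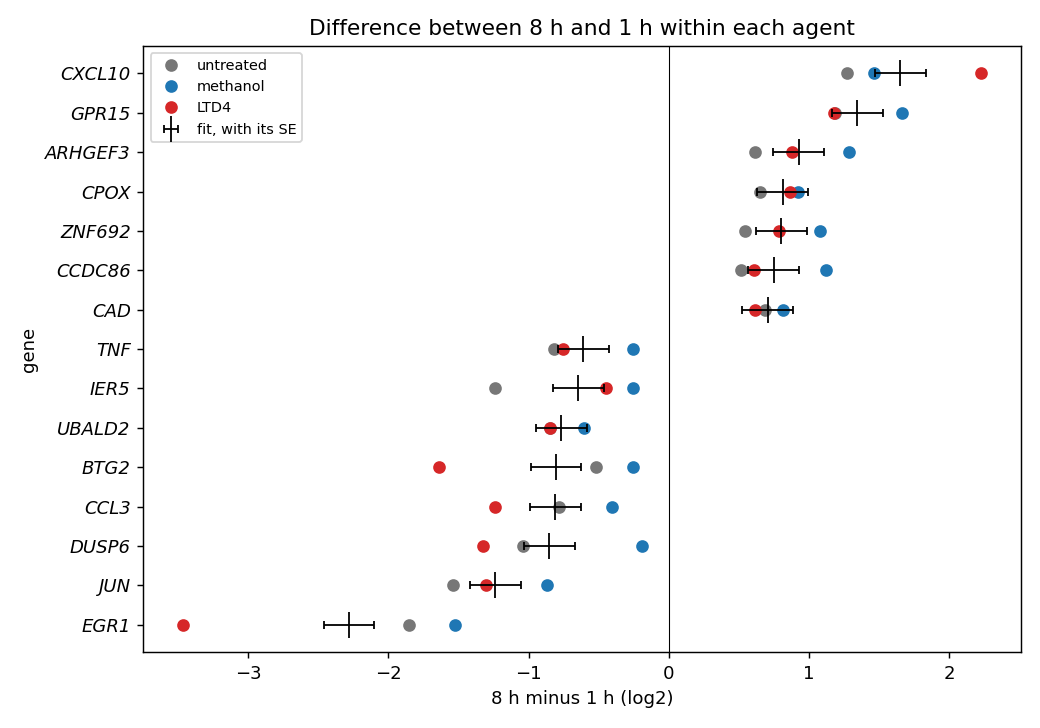
Difference between 8 h and 1 h (x axis, log2) for 15 named genes, with 1 point for each agent and a black mark with a bar for the fitted value and its standard error of 0.18. EGR1 spans -3.46 with LTD4 to -1.53 with methanol, and CXCL10 1.27 in untreated cells to 2.22 with LTD4.

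Among the other genes that rose were ZNF692 by 0.80, CCDC86, a nucleolar protein gene, by 0.75 and CAD, which starts pyrimidine synthesis, by 0.71, together with the small nucleolar RNAs SNORD50A by 1.10, SNORA21 by 0.90 and SNORD47 by 0.79. The other genes that fell included UBALD2 by 0.77, CES1 by 1.19, FAM110C by 0.91 and CTAG2 by 0.80. CES1 and CTAG2 were lower at 8 h in the untreated and methanol pairs but stood at 0.01 and -0.05 between the LTD4 arrays. Cholesterol and hypoxia lists had 0 members called by limma, but 2 and 1 lower after centring, with medians of -0.04 and -0.09. Camera gave both an adjusted p of 0.0289 with the preset correlation, and an adjusted p = 0.905 with an estimated correlation. The proliferation and DNA replication list had 0 calls of 21 and a median of 0.14. Of 17 lists tested, camera put 3 past the threshold with the preset correlation and 0 with an estimated one, and after centring 6 and 0.

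The time call depended on the arrays. Without both methanol arrays 9 genes were called, without both LTD4 arrays 19 and without both untreated arrays 187, and with a trend in eBayes 7 were called and without the agent block 5. EGR1, JUN, CXCL10 and GPR15 kept their direction and passed the threshold in each of 13 alternatives that could move them. Each other gene named for this comparison lost its call without the LTD4 or without the methanol arrays. Several of these differences kept their size: without the LTD4 arrays ARHGEF3 stood at 0.95, CCDC86 at 0.82, CPOX at 0.79 and CAD at 0.75.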

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

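The tests that weigh the 2 patterns below were chosen after the result was seen. In these results the LTD4 effect, LTD4 minus methanol, had opposite signs at 1 h and 8 h before centring or was a signal outside the genes analysed. Each effect is the difference of 2 single arrays, so the difference between the times was not tested. The genes below were picked, after their values were seen, from the 31 with a difference of at least 1 between the times.

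EGR1 differed by 1.74 at 1 h and -0.19 at 8 h, a difference of -1.94 between the times. KLF10 went from 1.52 to -0.18, a difference of -1.70, and BTG2 from 1.08 to -0.30, a difference of -1.38. The MAP kinase phosphatases followed, DUSP6 with -1.13 and DUSP2 with -1.13, and the AP-1 subunit JUNB with -1.10. At 8 h the effects of DUSP6, DUSP2 and JUNB were -0.0075, -0.16 and -0.19, and the median tested gene stood at -0.10. For these genes, EGR1 and KLF10 the effect at 8 h was near the median gene, so no reversed effect is shown. LTA4H, the leukotriene A4 hydrolase, went from 0.54 to -0.62, a difference of -1.15. SNORA31 had a difference of -2.06, and the differences of the 26 C/D box small nucleolar RNAs had a median of -1.05, with median effects of 0.42 at 1 h and -0.58 at 8 h. In the opposite direction stood CES1 with 2.02, from -1.50 to 0.51, and CTAG2 with 1.36, from -1.07 to 0.29. For SNORA31, CES1 and CTAG2 at 1 h the methanol array lay farther from the untreated one, at -1.37, 1.99 and 2.20, than the LTD4 array did, at 0.14, 0.49 and 1.14.

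Of 727 probesets outside the genes analysed and above the background limit, 1 at 1 h and 0 at 8 h differed from both references by at least 2-fold in the same direction. Probeset 8055305, without a gene symbol, on chromosome 2 at 132727197-132727348, was higher with LTD4 at 1 h by 1.14 against methanol and 1.44 against untreated. Its intensity at 8 h was 1286 with methanol, above the 612 with LTD4 at 1 h, so the array of 1 h was not its highest.

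The first pattern weighed is the higher level of immediate early genes on the LTD4 array at 1 h, with EGR1, KLF10, BTG2 and IER2 at its head. A uniform shift of the LTD4 array would move matched random lists as much. The list lay above them, which argues against that shift alone. After centring its lower median was 0.33, at percentile 100. Centring subtracts 1 value per array, so it cannot move the list relative to random lists and adds no support. The median of 0.25 against untreated cells, at percentile 99.99, argues against a low methanol array as the only source. Methanol minus untreated had a median of -0.34 for this list at 1 h, at percentile 5.45, with 4 of 19 positive. A low methanol array may therefore add to the difference from methanol. Spread between single arrays cannot be told apart from an effect of LTD4, because 1 array stands for each condition: 4 of the list's genes were above both other arrays by 1.5-fold on the LTD4 array at 1 h, against at most 1 on any other array taken as the odd one. After centring these counts were 3 and 1. The untreated array of 1 h then also had 2 of the list's genes below both other arrays, so it stood apart too. KLF10 and BTG2 passed the background limit on that LTD4 array alone, so the count partly follows from the filter. The same array had the highest antigenomic median of its time, 6.132 against 6.018 with methanol and 5.825 without treatment. All 26 measured C/D box small nucleolar RNAs were also higher on it than on both other arrays of 1 h. An early response to LTD4 through its receptor, the biological explanation the design offers, may account for the pattern and stays untested. The pattern was found and weighed on the same arrays, so this is a hypothesis.

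The second pattern is the higher level of C/D box small nucleolar RNAs such as SNORD41 and the lower level of RPPH1, RMRP, RNU4B1 and RNU5E-1 on the methanol arrays than on the untreated ones, while RNU2-1 and RNU2-2, 2 of the 7 members of the latter class, were higher. The gap between the 2 class medians, at least 2.46 at either time, follows from how the pattern was defined and decides nothing about a uniform gain or loss of short RNAs. A higher array background alone would raise control probesets that match no human sequence as much, but 13 bright ones differed by 0.03 at 1 h and 0.31 at 8 h against class medians of 0.51 and 1.19. More intron signal on the array could contribute to the small nucleolar RNAs, many of which lie in introns: over the 6 arrays their median followed that of intron control probesets with rho 0.886 (exact permutation p = 0.0333, two-sided, 0.0333 after Benjamini-Hochberg over 2 relations) and r 0.889 (exact permutation p = 0.0194, 0.0194 after adjustment), or r 0.835 without the 2 arrays farthest from the median. The antigenomic medians gave rho 1 (exact permutation p = 0.0028, 0.0056 after adjustment) and r 0.968 (exact permutation p = 0.0014, 0.0028 after adjustment), or 0.985 without 2 arrays, so the relation is not specific to introns. These medians reflect array background, so a contribution of background to the small nucleolar RNA levels stays open. Methanol itself and the unstated handling of untreated cells, whose arrays serve as reference for both agents, stay open as well.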

How the results depend on the processing

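The fit on centred values without both untreated arrays, the 1.5-fold limit on centred values and the counts with another array taken as the odd one were chosen after seeing the data. Unless a construction is named, the cause was not tested. Each group held 1 array, so leaving out an array leaves a lone one that is assumed to vary like the rest.

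EGR1, JUN, CXCL10 and GPR15 kept direction and threshold between 8 h and 1 h in 13 of 13 alternatives that could move them, EGR1 between -2.71 and -1.69. RPPH1, RMRP, RNU4B1, RNU5E-1, SNORD41 and CTAG2 did so for methanol against untreated in 14 of 14. At 1 h, which had no test, EGR1 and KLF10 stayed above 2-fold against methanol in the 4 alternatives that could move them, EGR1 at 1.58 or more, and BTG2 fell short at 0.97 after centring. Of single-gene values tested under such alternatives, 430 kept direction and side of the threshold, 87 lost the threshold, 2 passed it and 3 reversed. The reversed ones, in LTD4 against methanol over both times, were CYSLTR1, at -0.01 without the LTD4 array of 8 h and -0.10 without the methanol array of 1 h, and EGR1, at -0.11 without the LTD4 array of 1 h, which by construction leaves 8 h as the only time measured with LTD4.

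Without a filter, which tests more and dimmer genes, counts were 320 for 8 h against 1 h (62 higher, 258 lower), 13 for LTD4 at 1 h, 3 for LTD4 at 8 h, 3 for LTD4 against methanol over both times, 212 for the difference between the times (135 positive, 77 negative), and for methanol against untreated 376 at 1 h (338 higher, 38 lower), 708 at 8 h and 1673 over both times. With the filter on the mean they were 133 (42 higher, 91 lower), 8, unchanged at 8 h, 1, 77, 158, 372 and 580. At 1.5-fold, a lower bar by construction, they were 15 and 2 for LTD4 at 1 h and 8 h (10 and 2 when centred), 255 for the difference, and 349 and 552 for methanol. Centring gave 157 for time, 39 for methanol at 8 h and 398 over both times. Quantile normalization gave 147, 40 and 382 there and 5 for LTD4 at 1 h.

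For LTD4 at 1 h and 8 h, methanol alone as reference gave 10 and 2, untreated alone 34 and 98, and their mean 10 and 8. The methanol array as the odd one gave 5 and 2, and the untreated array 21 and 58.

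For 8 h against 1 h, robust eBayes gave 28 genes, a trend 7 and no block 5. Leaving out 1 array gave 9 to 187, and, since the block then drops its partner, leaving out both arrays of an agent gave the same: 19 without LTD4, 9 without methanol and 187 without untreated (167 higher, 20 lower). Centred and without both untreated arrays it was 153. For methanol against untreated a trend gave 52, and leaving out 1 array gave 38, without methanol at 8 h, to 343, without untreated at 1 h. It gave 47 without either LTD4 array. For LTD4 against methanol leaving out 1 array gave 0 to 2: 1 without the LTD4 array of 8 h and 2 without either untreated array, and EGR1 passed in each of these. Over single arrays left out EGR1 ranged from -0.11 to 1.66, without the LTD4 array of 8 h, and CYSLTR1 from -0.10 to 0.25.

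The second deposited table held the same values and tests nothing. Signal over background limits dim genes such as NR4A3 and FOSB, which lay below 1263 on every array.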

Other observations

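The tests on the gene lists below were set before the data were examined, and so was the count of other splits of the arrays.

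Heat shock genes, led by HSPA1B and DNAJB1, had a median of 0.21 for LTD4 minus methanol at 1 h, at percentile 99.53, with 12 of 12 positive, but of -0.18 against untreated, at percentile 10.66. FOXO and growth factor withdrawal genes, led by TSC22D3 and CCNG2, had a median of 0.26 at percentile 97.92, and of -0.03 against untreated, at percentile 70.93. At 8 h the FOXO median against methanol was -0.24, at percentile 5.53, or -0.22 at percentile 1.66 without the filter. Proliferation genes, among them PLK1 and MCM2, had a median of 0.07 against methanol, at percentile 11.25, and of -0.26 against untreated, at percentile 1.07. At 8 h their median against methanol was -0.18, at percentile 1.8. Fatty acid synthesis genes, led by FASN at 1 h and SCD at 8 h, had medians of 0.13 at percentile 55.23 at 1 h and -0.22 at percentile 3.07 at 8 h. Against untreated they were -0.39 at percentile 0.41 and -0.18 at percentile 1.32, or percentiles 7.08 and 1.52 without the filter. Methanol minus untreated at 1 h had medians of -0.43 at percentile 0.35 for heat shock and -0.45 at percentile 2.14 for fatty acid genes. Without the filter these percentiles were 0.8 and 13.44. Without the filter the percentiles at 1 h against methanol and untreated were 99.68 and 20.3 for heat shock, 96.8 and 15.22 for FOXO and 19.34 and 0.31 for proliferation genes, and those at 8 h against methanol were 2.81 for proliferation and 5.3 for fatty acid genes.

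Other lists for LTD4 minus methanol had these medians at 1 h and 8 h. Cholesterol genes had 0.14 at percentile 75.47 and -0.05 at percentile 78.29. Hypoxia genes such as SLC2A3 had 0.18 at percentile 90.67 and -0.15 at percentile 12.65, and without the filter percentiles 96.82 and 31.95. Stress response genes such as HERPUD1 had 0.11 at percentile 44.1 and -0.04 at percentile 73.8, or percentiles 80.51 and 84.94 without the filter, and oxidative stress genes such as TXN 0.18 at percentile 86.76 and -0.02 at percentile 60.59. Genes of formaldehyde metabolism such as MTHFD1 had 0.06 at percentile 22.3 and 0.02 at percentile 91.05, transporters such as SLC38A2 0.12 at percentile 53.83 and 0.03 at percentile 84.88, and housekeeping genes such as ACTB 0.15 at percentile 78.72 and -0.08 at percentile 10.83. Without the filter the formaldehyde list stood at percentiles 67.63 and 98.19. Calcium, NFAT and CREB targets stood at -0.07, percentile 67.72, and Hodgkin cell markers at -0.14, percentile 11.55, at 8 h.

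Some lists had too few measured members for a percentile. The ERK list had 2 (DUSP6 and DUSP2, with all members given in the comparison at 1 h), B-cell identity 2 (PAX5 and TCF3, median 0.03 at 1 h), p53 targets 2 (BTG2 and TIGAR) and the interferon response 1 (IFI6, -0.06 at 1 h and -0.23 at 8 h). Without the filter 19 interferon genes had medians against methanol of 0.005 at percentile 69.26 at 1 h and -0.20 at percentile 1.42 at 8 h. Their 8 h median against untreated was 0.20, at percentile 8.98. Of markers of other cell types, 0 of 11 T-cell, 0 of 11 monocyte and macrophage, 0 of 9 epithelial and 0 of 6 erythroid genes passed the background limit. Of 10 fibroblast and endothelial markers PECAM1 and CDH5 passed, PECAM1 with an intensity of 5781 on the untreated array of 1 h.

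Across the 3584 genes, which are not independent replicates, methanol minus untreated at 1 h and at 8 h correlated with r 0.702, LTD4 minus untreated with r 0.619 and LTD4 minus methanol with r -0.419. The 2 LTD4 minus methanol differences share no array.

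The 6 arrays can be split into 3 and 3 in 10 ways. In 1 of them, the real split by time, limma called 63 genes, EGR1 and CXCL10 among them, and the highest of the others called 6, and 10 splits are too few for a share under 0.05.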
